A study of Arabidopsis thaliana with 26 samples.

How the data were processed

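The series holds 26 samples, of which 5 were analysed. The 21 small RNA, mRNA and ChIP samples were not analysed here. The samples analysed were 3 bisulfite libraries (Col, crt1-4 and crh6-3, leaf per the labels) and 2 Hi-C libraries (WT and crh6), with 1 library per group. The labels of the Hi-C samples conflict on the tissue, since the source and tissue labels say floral and the treatment protocol says seedling leaves. The labels do not say which crh6 allele was used for Hi-C or whether libraries were pooled.

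The deposited bisulfite values are a methylation fraction per cytosine, from 0 to 1, with chromosome, 1-based position on TAIR8, context and strand per the names of the files. No read counts are given, so the coverage behind each fraction and any coverage minimum are unknown, and the bisulfite aligner is not given in the sources used here. The deposited Hi-C values are a signal, per the file headers a matrix corrected for coverage by iterative correction of all chromosomes together, at 200 kb and 50 kb on TAIR8. The headers also name an excluded blacklist, a filter by SD and exact read matches. Bowtie is named in the submitters' processing notes, without a version. All kept bins of a matrix had the same total, which was checked on the values, and filtered bins had no value.

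Methylation levels were unweighted means over the cytosines listed in all 3 libraries, by context. Pericentromeres were the run of 200-kb bins around each chromosome's bin of highest Col CHG methylation with a mean CHG fraction of 0.15 or more, with gaps of up to 2 bins bridged. The rest of each chromosome was called arm. Windows of 200 bp with at least 4 shared cytosines of the context and at least 1 on each strand were called different when the mean fraction differed by at least 0.4 (CG), 0.2 (CHG) or 0.1 (CHH) and both strands moved the same way. Named regions were, for each mutant and context, the 5 with the largest rise and the 5 with the largest fall among windows with at least 20 shared cytosines in which both strands moved the same way and neither strand moved by less than 50% of the other. Adjacent windows were merged. For the change by level, CHH windows were placed by the mean of the 3 libraries on 1 strand and read on the other strand. Where fewer than 5 such regions passed the window threshold, the list was filled with regions that did not pass it. Windows shared by both mutants were counted beside the same count with each other library in the shared role, and beside 20 draws in which the 3 libraries were made exchangeable around their mean level, with a spread taken from the difference of the mutants, which can hold real differences. CHH windows with at least 5 shared cytosines on each strand that were lower in both mutants by 10 percentage points or more on 1 strand were also read on the other strand, each strand in turn, which was chosen after the data were seen.

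Hi-C values were scaled to a total of 1000 per bin, and log2 values were taken after adding 0.1. Classes of bin pairs left out pairs within a bin and with its neighbours. Whole contacts were recovered from the 50-kb matrices by finding a factor for each bin that makes the values whole. Within 0.05 of a whole number were 99.9956% of the WT values and 99.9749% of the crh6 values. These contacts served for depth, for 95% intervals, which come from Poisson variances for ratios and are Wilson intervals for shares, and for balancing anew. For 1 comparison of depth, WT contacts were thinned at random to 8131092. The compartment axis was the first principal component of the correlation matrix of each chromosome. Named bins were the 5 with the largest rise and the 5 with the largest fall of contacts with pericentromeres of other chromosomes, and named pairs were the 5 highest between arms in each library.

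The design, the thresholds, the rule for named regions and most of the other settings tried were fixed before the data were examined. The corrections for the level of unmethylated windows, (m - b) / (1 - b) and plain subtraction of b, where b is the mean level of windows with CG below 2%, were added after the data were seen. So were the log2 ratio of class means and the uses of recovered contacts, including balancing without near contacts. Medians of genes and transposon genes and 4 gene lists were not analysed here, because the gene table used here gives no TAIR8 positions.

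The window calls were tested on simulated data from chromosome 4 with an assumed 10 reads per cytosine. Simulated falls of 0.5 in CG, 0.3 in CHG and 0.15 in CHH were called in 95.5%, 96% and 93.5% of 200 windows, and 2 of 71837, 204 of 74674 and 36 of 89451 unchanged windows were called. In a simulated Hi-C experiment, a log2 change of -0.3 within pericentromeres came back as -0.21 after balancing, with 0.04 between pericentromeres where none was simulated. The software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.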

Results

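CRT1 (also MORC1) and CRH6 (also MORC6) are ATPases of the MORC family, which the series' title links to heterochromatin condensation and gene silencing in Arabidopsis thaliana. Of the 26 samples in the series, 5 were analysed. They comprised 3 whole-genome bisulfite libraries from leaf (Columbia wild type, called Col, and the T-DNA insertion mutants crt1-4 and crh6-3) and 2 Hi-C libraries (wild type, called WT, and crh6). Bisulfite sequencing gives the share of copies of a cytosine that are methylated, and Hi-C counts ligated pairs of DNA fragments as a measure of how often 2 loci lie close together. Every group held 1 library, so no value below has a replicate error and no test across samples was made. The SD values given are over the 5 chromosomes of a pair of libraries and are not replicate errors. The bisulfite files listed 36575220 cytosines for Col, 39061760 for crt1-4 and 38904784 for crh6-3, of which 35818104 were listed in all 3. They gave no read counts, so the depth behind each methylation value is unknown and no interval was computed. The Hi-C matrices corresponded to 12426103 contacts for WT and 8132889 for crh6, recovered from the corrected values. The intervals given for Hi-C cover counting error only.

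The first comparison asked whether DNA methylation differed from wild type in either mutant. CHH methylation, the context in which C is followed by 2 bases other than G, was lower in both mutants. Over the genome it was 2.19% in Col, 1.98% in crt1-4 and 1.88% in crh6-3. The difference from Col was -0.205 percentage points in crt1-4 (SD 0.0191) and -0.304 in crh6-3 (SD 0.0206), and all 5 chromosomes were lower in each mutant. These differences were -9.38% and -13.9% of the Col level. CG and CHG methylation differed less from Col in relative terms. Genome CG was 25.2% in Col, 25.2% in crt1-4 and 25.1% in crh6-3, and genome CHG was 7.40%, 7.35% and 7.18%.

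Pericentromeres, the transposon-rich heterochromatin around the centromeres, differed little from Col in CG and CHG methylation. They were taken as the blocks of high Col CHG methylation at 12600001 to 16800000 on chromosome 1, 1200001 to 7000000 on chromosome 2, 10800001 to 16000000 on chromosome 3, 1600001 to 6000000 on chromosome 4 and 9800001 to 14600000 on chromosome 5 (TAIR8). Pericentromeric CG was 69.8% in Col, 70.3% in crt1-4 and 70.2% in crh6-3, which was higher by 0.442 (SD 0.0380) and 0.375 (SD 0.0720) percentage points. Pericentromeric CHG was 30.8% in Col, 30.9% in crt1-4 and 30.8% in crh6-3. Pericentromeric CHH was 6.84% in Col, 6.43% in crt1-4 and 6.19% in crh6-3, with differences of -0.410 (SD 0.0379) and -0.644 (SD 0.0332) percentage points. In the chromosome arms CHH was 1.20% in Col, 1.04% in crt1-4 and 0.969% in crh6-3, with differences of -0.162 and -0.231 percentage points. Arm CHG was 2.83%, 2.74% and 2.57% in the same order, and arm CG was 15.6%, 15.5% and 15.4%.

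**Figure D1:**
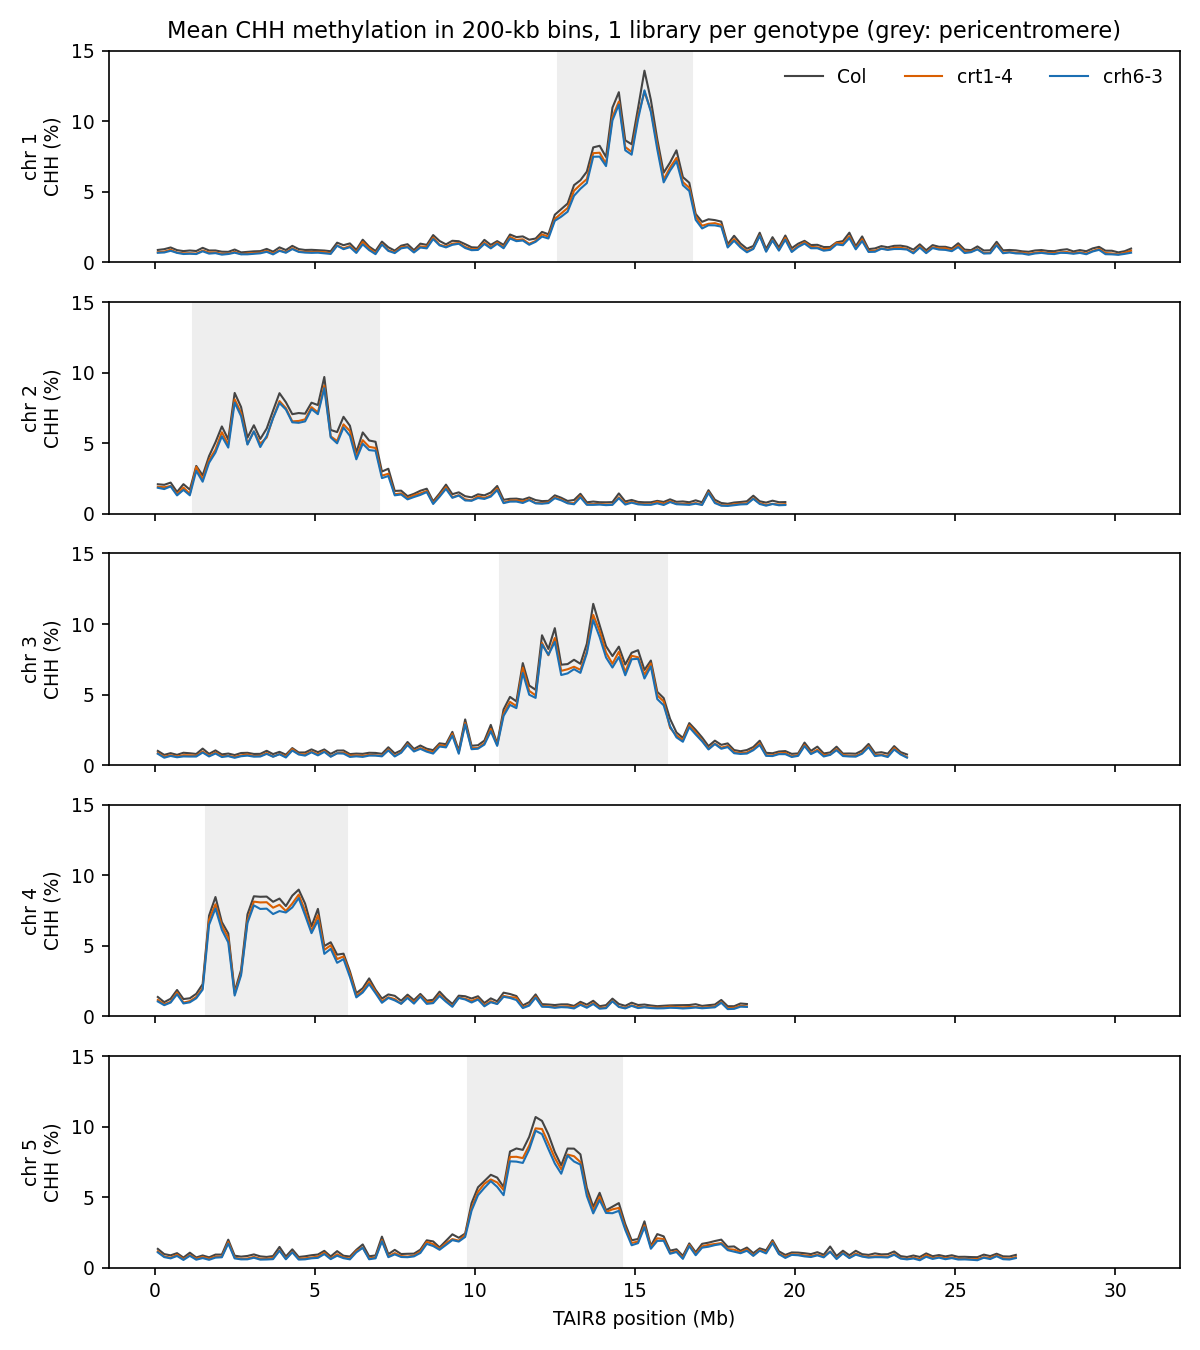
CHH methylation level (percent) in 200-kb bins along the 5 chromosomes (position in Mb), with a line for each of the Col, crt1-4 and crh6-3 bisulfite libraries. The level was highest in the pericentromeres, where the means were 6.84% in Col, 6.43% in crt1-4 and 6.19% in crh6-3.

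Unmethylated DNA differed between the libraries as well. In 222912 windows of 200 bp with a CG level below 2%, CHH was 0.713% in Col, 0.582% in crt1-4 and 0.535% in crh6-3. CHG in these windows was 0.871%, 0.784% and 0.641%, and CG was 1.13%, 1.03% and 0.914%. After levels were corrected for the level of these windows, the genome CHH difference was -0.0774 percentage points in crt1-4 (SD 0.0195) and -0.129 in crh6-3 (SD 0.0212), or -5.21% and -8.68% of the corrected Col level. The corrected pericentromeric CHH difference was -0.290 in crt1-4 and -0.479 in crh6-3, and that in arms was -0.0322 and -0.0546, against -0.162 and -0.231 before. For genome CG the correction turned the direction, with 0.0588 percentage points in each mutant against -0.0136 and -0.104 before. For genome CHG it gave 0.0274 in crt1-4 against -0.0540 before, and -0.00245 (SD 0.00972) in crh6-3 against -0.217 before. The corrected CHG difference of crh6-3 was 0.172 in pericentromeres and -0.0366 in arms. With the level of these windows subtracted instead, genome CHG in crh6-3 was 0.0127 and so also turned. Both corrections were chosen after the data were seen. CHH windows whose level was 10 to 20% were lower by more than the unmethylated windows, with -0.612 percentage points in crt1-4 and -1.002 in crh6-3.

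At single loci, most 200-bp windows that passed the CHH threshold were lower in the mutants. Of 572644 windows tested in CHH, 702 were lower and 218 higher in crt1-4, and 865 were lower and 176 higher in crh6-3. In CHG, 802 windows were lower and 533 higher in crt1-4, and 1002 were lower and 571 higher in crh6-3, of 478424 tested. These CHG calls were 0.279% and 0.329% of the windows tested, near the 0.273% called among unchanged windows simulated with an assumed 10 reads per cytosine, while the true depth is unknown. Over all settings for windows, 52.3 to 74.9% of the CHG calls were lower, with the lowest share in crt1-4 with at least 10 shared cytosines (91 of 174) and the highest in crh6-3 with 500-bp windows (373 of 498). CG windows went both ways more evenly, with 1869 lower and 1565 higher in crt1-4 and 1405 lower and 1185 higher in crh6-3, of 461441 tested. The mutants also differed from each other, in 3962 CG, 929 CHG and 493 CHH windows. The number of windows depended on their size, with 127 CHH windows in crt1-4 and 149 in crh6-3 when they were 500 bp long, and 3199 and 3650 when they were 100 bp long.

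The second comparison asked whether the mutants differed from Col at the same places. The same direction in both mutants was seen in 416 CHH windows, 380 of them lower, in 499 CHG windows, 377 of them lower, and in 906 CG windows, 513 of them lower. Over all settings, 63.2 to 85.8% of the shared CHG windows were lower, from 48 of 76 with at least 10 shared cytosines to 169 of 197 with 500-bp windows. Both comparisons share the Col library, so the count was set beside those with another library in the shared role. In CHH, crt1-4 differed the same way from the other libraries in 131 windows and crh6-3 in 118. In CHG these counts were 221 and 283, below the 499 of Col. In CG they were 1644 and 1052, above the 906 of Col. In 20 draws without any difference between the libraries, 98 to 148 CHH windows, 181 to 226 CHG windows and 628 to 718 CG windows were shared in this way. The draws gave all 3 libraries the spread between the mutants, so they do not cover a Col library with more noise. In pericentromeres, 152 of 107194 windows tested in CHH and 196 of 82406 in CHG were lower in both mutants. In arms these were 228 of 465450 and 181 of 396018. Their share of the windows tested was thus larger in pericentromeres, where CHG and CHH levels were higher.

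The CHH regions with the largest fall from Col lay in pericentromeres and arms. They were chosen against the Col library that both mutants share, so a low level in both mutants can come from a high Col value. At 18081201 to 18081400 on chromosome 3, CHH was 23.4% in Col, 1.09% in crt1-4 and 0.571% in crh6-3. At 6743801 to 6744000 in the pericentromere of chromosome 2 it was 25.6%, 1.56% and 0.5%. At 7090001 to 7090200 on chromosome 4 it was 26.5% in Col and 26.2% in crt1-4 but 0.576% in crh6-3. Regions with more CHH than Col were found too. At 3063401 to 3063600 on chromosome 3, CHH was 0.455% in Col, 16.6% in crt1-4 and 17.2% in crh6-3, and at 13377401 to 13377600 on chromosome 4 it was 0.918%, 23.6% and 0.364%.

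CG regions with the largest fall mostly had it in 1 mutant alone. Of the 5 CG regions with the largest fall, 1 passed the threshold in the other mutant for crt1-4 and 1 for crh6-3. At 19967401 to 19967600 on chromosome 1, CG was 89.0% in Col, 0.172% in crt1-4 and 78.0% in crh6-3. At 14106601 to 14106800 in the pericentromere of chromosome 5 it was 91.1%, 85.1% and 1.97%, and at 22988601 to 22988800 on chromosome 1 it was 83.8%, 85.7% and 0.625%. At 19216201 to 19216400 on chromosome 5, CG was 13.4% in Col but 85.7% in crt1-4 and 89.6% in crh6-3. In CHG, the region at 22598601 to 22598800 on chromosome 5 had 39.6% in Col, 4.48% in crt1-4 and 14.3% in crh6-3. The region at 2804001 to 2804200 in the pericentromere of chromosome 4 had 39.8%, 36.9% and 1.46%. Among the named CHG regions with a fall, 1 passed the window threshold in crt1-4, and the other 4 of its list did not. The named regions with a rise reached 78.4 percentage points in CG, 28.2 in CHG and 22.6 in CHH. Which genes or transposons these regions hold was not analysed here.

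The third comparison asked whether the folding of the genome differed between WT and crh6. Contacts within a pericentromere were fewer in crh6 on all 5 chromosomes. Their mean corrected value was 11.9 in WT and 9.56 in crh6 on a scale where each bin totals 1000, a mean log2 change of -0.33 (SD 0.09), or 0.793-fold, and the chromosomes ranged from -0.41 to -0.20. The ratio of means in the 50-kb matrices was -0.32 (95% counting interval -0.32 to -0.31). Contacts within an arm were also fewer, by less (-0.19, SD 0.01). Before balancing, the recovered contacts were 415936 in WT and 240408 in crh6 within pericentromeres, and 3210224 and 1856237 within arms. These counts fell in about the same proportion, so the larger fall within pericentromeres than within arms was seen only after balancing. Contacts between pericentromeres of different chromosomes were fewer as well (-0.11, SD 0.02), while those of pericentromeres with arms of other chromosomes were slightly more (0.02, SD 0.01). A pair between chromosomes counts for both of them, so these SD values come from overlapping sets, unlike those within chromosomes.

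Contacts between a pericentromere and an arm of the same chromosome had a mean log2 change of -0.09, those between opposite arms -0.08 and those between arms of different chromosomes -0.06. Contacts within a 200-kb bin took up 19.5% of the bin total in WT and 23.2% in crh6, and other bins of the same chromosome beyond the neighbours 43.8% and 40.0%. When contacts within a bin and with its neighbours were left out before balancing, which was chosen after the data were seen, the change within pericentromeres was -0.18 (SD 0.08), that within arms -0.13, and that between pericentromeres 0.0012, so that the last no longer had a direction. Under the same setting pericentromere with arm of the same chromosome turned to 0.020, opposite arms had -0.014 and arms of different chromosomes -0.00012, so these falls were no longer seen either. Contacts of pericentromeres with arms of other chromosomes had 0.11. In the 50-kb matrices the mean of log2 values for this class was -0.05, but the log2 ratio of means, which needs no added value where pairs are 0, was 0.060 (95% counting interval 0.053 to 0.068).

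**Figure D2:**
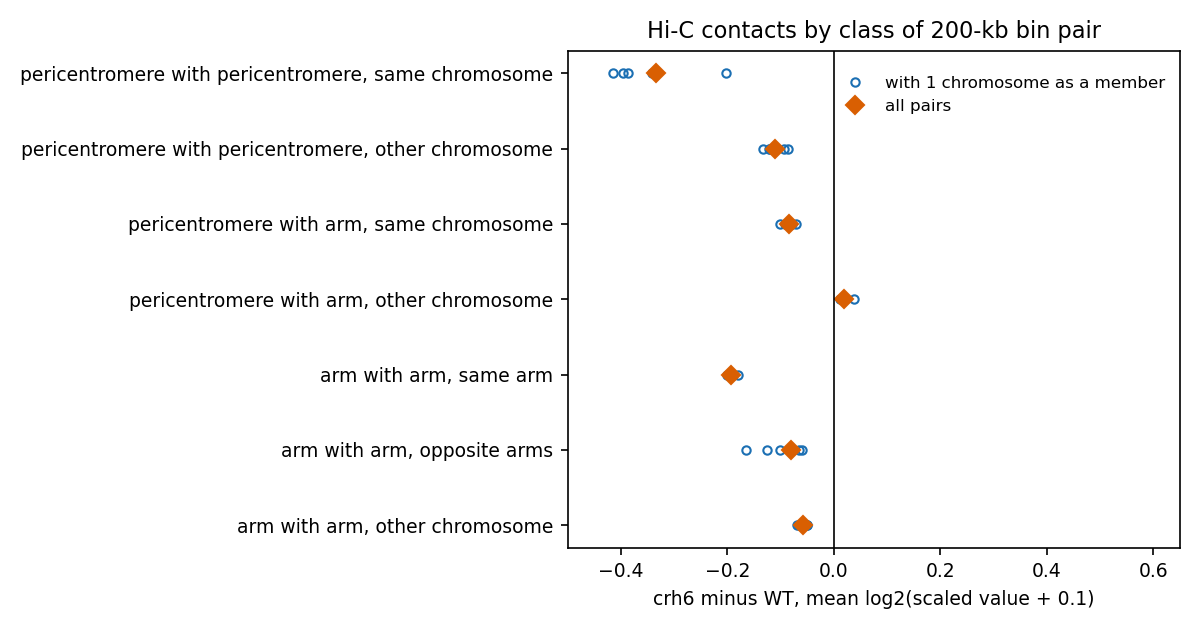
Change of Hi-C contacts from WT to crh6 (mean log2 difference, horizontal axis) for 7 classes of 200-kb bin pairs, where open circles are pairs with 1 of the 5 chromosomes as a member and diamonds are all pairs of the class. Contacts within pericentromeres had the largest change, at -0.33, with the chromosomes from -0.41 to -0.20.

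Contacts within pericentromeres were fewer in crh6 at distances below 4 Mb, and by more than contacts within arms at the same distances. The change was -0.21 at 0.4 to 0.6 Mb, -0.27 at 0.6 to 1 Mb, -0.35 at 1 to 2 Mb, -0.40 at 2 to 4 Mb and -0.17 at 4 to 8 Mb, where the SD over chromosomes was 0.221. In arms the change was -0.0018, -0.02, -0.07, -0.16 and -0.27 over the same distances. When near contacts were left out before balancing, the change within pericentromeres was smaller, with -0.050, -0.099, -0.18, -0.26 and -0.091, and that in arms was 0.068, 0.044, -0.0051, -0.097 and -0.20. None of 272 arm blocks as long as the pericentromere of their chromosome changed as much. These blocks were taken in steps of 200 kb and overlap, so they are not 272 independent comparisons. The pericentromeres lay -0.25 (SD 0.09) from the median of these blocks. Without near contacts this difference was -0.16 (SD 0.08), and 1 block, on chromosome 2, lay at or below its pericentromere.

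**Figure D3:**
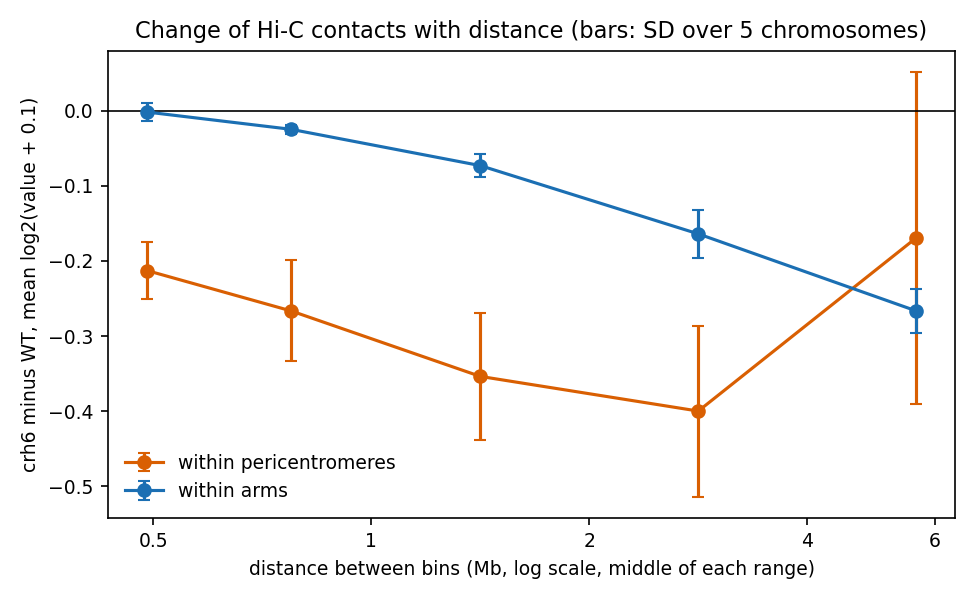
Change of Hi-C contacts from WT to crh6 (mean log2 difference, vertical axis) against the distance between bins (Mb, log axis) within pericentromeres and within arms, where points are means over bin pairs and bars are the SD over 5 chromosomes. At 1 to 2 Mb the mean was -0.35 in pericentromeres and -0.07 in arms.

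**Figure D4:**
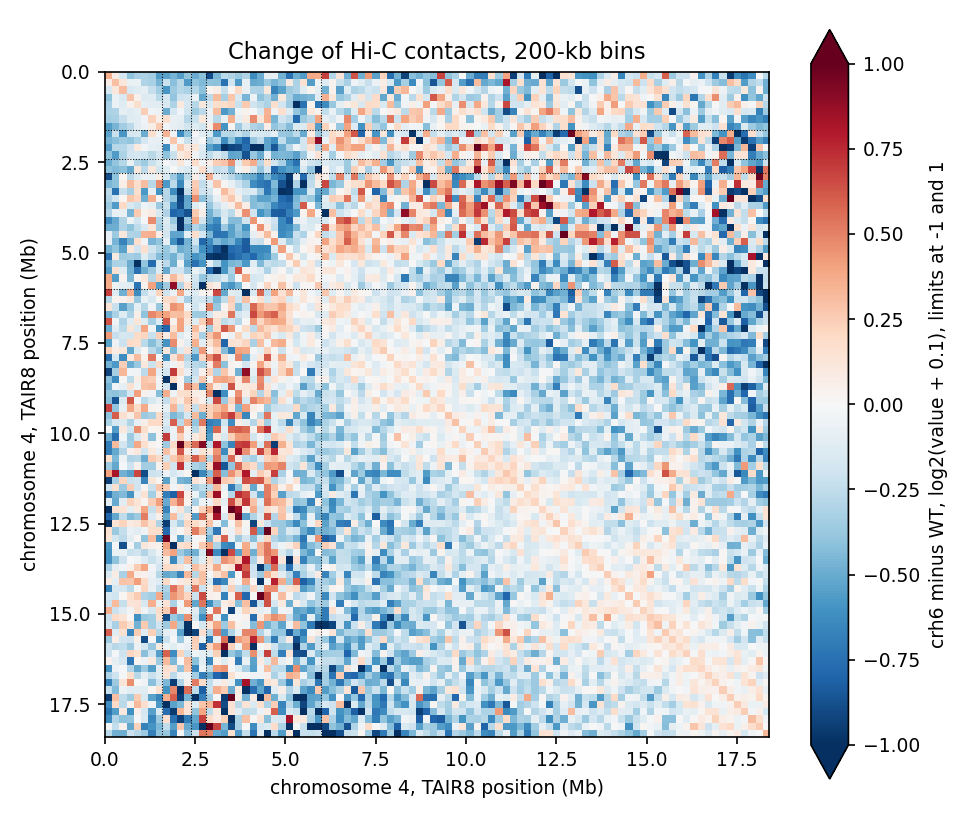
Change of Hi-C contacts from WT to crh6 (log2 difference, colour, limited to -1 and 1) between 200-kb bins of chromosome 4, with position in Mb on both axes. The block of pairs inside the pericentromere, 1600001 to 6000000, had a mean change of -0.34.

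The separation of heterochromatin from arms was visible in both libraries. The first principal component of each chromosome's contact pattern followed Col CHG methylation across bins with a mean Pearson r of 0.841 in WT (SD 0.156) and 0.752 in crh6 (SD 0.133), where bins are not independent replicates. On chromosome 5 r was 0.951 in WT and 0.659 in crh6 at 200 kb, and 0.704 and 0.347 at 50 kb. On chromosomes 1 to 4 r at 200 kb was 0.567, 0.877, 0.918 and 0.892 in WT. In crh6 it was 0.564, 0.852, 0.824 and 0.859, so lower on each. Spearman rho rose there instead, from 0.602, 0.717, 0.634 and 0.335 to 0.698, 0.777, 0.666 and 0.343. On chromosome 5 rho was 0.649 in WT and 0.484 in crh6. The difference of the mean r between the libraries was smaller than the SD over chromosomes, which is not the spread of the paired change. Contacts with the pericentromeres of other chromosomes were fewer in crh6 for 91 of 112 pericentromeric bins (median -0.12) and more for 265 of 471 arm bins (median 0.02). When near contacts were left out before balancing, they were fewer for 56 of 114 pericentromeric bins (median 0.0018) and more for 352 of 471 arm bins (median 0.11), so the fall of the pericentromeric bins was no longer seen. Across 583 bins the change had Pearson r of -0.360 and Spearman rho of 0.0630 with Col CHG methylation, so the relation was not a steady one.

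Among single bins, 4 of the 5 with the largest fall in these contacts were pericentromeric. The bin at 4800001 to 5000000 on chromosome 2 had -0.42, and those at 14200001 on chromosome 1, 12200001 on chromosome 5 and 3800001 on chromosome 2 had -0.33, -0.32 and -0.31. The fifth, at 19000001 to 19200000 near the end of chromosome 2, had -0.35. The 5 bins with the largest rise all lay in arms, at 12400001 and 12200001 on chromosome 2 and at 25800001, 21800001 and 21600001 on chromosome 1, with 0.30 to 0.31. In the 50-kb matrices the 5 rises were 0.052 to 0.089, and the falls were -0.22, -0.15, -0.19 and -0.23 for the pericentromeric bins in the order given and -0.15 for the fifth. Without near contacts the bin at 14200001 on chromosome 1 had 0.0018, so its fall was no longer seen, that at 3800001 on chromosome 2 had -0.16 and that at 21600001 on chromosome 1 had 0.47. Of the 5 strongest contacts between different arms, 4 in WT and 5 in crh6 joined chromosome ends. The first 200 kb of chromosomes 1 and 3 had 13.5 in WT and 18.8 in crh6, those of 3 and 5 had 12.4 and 18.6, and those of 1 and 5 had 13.5 and 17.6. Pairs of chromosome ends, the outer 1 Mb of each arm, had no such rise as a whole, with a mean log2 change of -0.018 over 1000 pairs of different chromosomes, of which 52.6% were higher in crh6. The left end of chromosome 1 with its bin at 30200001 had 13.4 and 13.5, the bin pair 1800001 and 22400001 of chromosome 3 had 10.6 and 10.7, and the left end of chromosome 3 with its bin at 23200001 had 10.2 and 12.2.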

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

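The tests of the explanations below were chosen after the results were seen, except that of contacts within a bin as a reason for fewer pericentromeric contacts, whose expected outcome was written down before its value was known.

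CHH methylation was lower in both mutants, and a lower level of miscalled cytosines in the mutant libraries would lower all windows alike, whereas CHH windows of 10 to 20% methylation were lower in crt1-4 by more than unmethylated windows (-0.612 against -0.130 percentage points), which argues against it as the whole reason but not as part of it (genome CHH was -0.205 before and -0.0774 after correction). Read noise in the shared Col library was argued against as the whole reason for windows lower in both mutants. In 1557 cases chosen on 1 strand the other strand had -3.42 (SD 0.625) percentage points in crt1-4 and -3.98 (SD 0.673) in crh6-3. These lie beyond the largest mean change at any CHH level (-1.30 and -2.07). In 58.0% of these cases both mutants also moved the same way on the other strand, against 31.6 to 43.6% in the other groups of cases chosen in this way. Where both mutants were higher than Col (223 cases), the other strand had 1.13 (SD 1.07) in crt1-4 and -0.176 (SD 1.13) in crh6-3. That rise was thus not repeated in both mutants. With both others above crt1-4 the other strand moved by 2.77 (SD 1.44) in Col and 1.43 (SD 1.77) in crh6-3. Above crh6-3 it moved by 2.17 (SD 0.475) in Col and 1.14 (SD 0.567) in crt1-4. With both others lower, the values were 0.117 and -1.53 for crt1-4 and 0.633 and -0.444 for crh6-3. So a Col library high at these places cannot be told from a fall in the mutants. Chance in part stays open there, since the cases were chosen by a fall of at least 10 points. For the lower genome CHG level of crh6-3 the corrected difference of -0.00245 percentage points decided nothing. It balanced 0.172 in pericentromeres against -0.0366 in arms (SD 0.00570, lower on 5 of 5 chromosomes). The arm value does not decide on miscalling either, since its SD does not cover error in the level of unmethylated windows. In arms, CHG of crh6-3 changed by -0.224 in unmethylated windows and by -0.258 in windows with CG methylation alone. That gap is about as large as the arm value. Arm windows methylated in all contexts had -0.483, a larger fall than either, for which no SD was computed. A loss of CHH methylation through the mutations and a difference between single libraries other than genotype cannot be told apart, because each genotype had 1 library.

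Contacts within pericentromeres were fewer in crh6, and lower depth of the crh6 library was argued against by a change of -0.35 after WT was thinned to the crh6 total. A steeper decline with distance along all of the genome was argued against, as the whole reason for the balanced values, by arm blocks. Pericentromeres differed from arm blocks of their length by -0.26, or by -0.16 (SD 0.08) without near contacts. This cannot tell a loss of pericentromeric contacts from the larger pericentromeric share of contact ends in crh6, which balancing turns into lower values. More contacts formed within 1 bin of crh6 may account for part of the change but not all of it, since -0.18 (SD 0.08) remained when near contacts were left out before balancing. More random ligation in crh6 stayed open, because the change of -0.11 between pericentromeres became 0.0012 without near contacts, and contacts between chromosomes then took up 35.0% of the total in WT and 36.8% in crh6, while over all contacts, where contacts within a bin enter the total, they took up 24.2% and 24.0% of the corrected 200-kb values and 21.0% and 20.1% of recovered contacts. Looser packing of pericentromeres through the mutation and a difference between single libraries other than genotype cannot be told apart, because each genotype had 1 library.

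The pericentromeric share of recovered contact ends was higher in the crh6 library than in the WT library for some kinds of contacts. Over all contacts it was 15.5% in WT and 16.4% in crh6. Balancing gives all bins the same total, so a larger share lowers the corrected values of pericentromeric pairs. The share thus enters every comparison of corrected Hi-C values above. Within 50-kb bins this share was 14.4% in WT (95% Wilson interval 14.3 to 14.4) and 16.0% in crh6 (16.0 to 16.1), where the intervals cover counting error only and cannot show a difference between genotypes with 1 library each. More contacts formed within 1 bin could raise that share alone, but the share in contacts between chromosomes was also higher, by 0.092 on the log2 scale (SD 0.05), on all 5 chromosomes. In contacts of the same chromosome more than 200 kb apart the share was 15.6% in WT and 15.7% in crh6, a log2 difference of 0.0084 (SD 0.040). Easier cutting or ligation of pericentromeric DNA in crh6 and a difference in read mapping between libraries were not tested.

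In 10 CG windows the mutants differed from Col in opposite directions, with crt1-4 lower in 9 of them and higher in the window at 7974601 on chromosome 2. The window at 25599201 on chromosome 1 held 9 shared cytosines and the others 4, the minimum. The number of opposite windows that unrelated calls would give was not computed, and the difference between mutants was not tested. The 3 such CHG windows, named after their values were seen, were at 13360401 on chromosome 1 (37.0% in Col, 1.04% in crt1-4 and 65.0% in crh6-3), 13724601 on chromosome 2 (32.3%, 0.595% and 67.9%) and 18265601 on chromosome 3 (24.4%, 2.33% and 54.1%), and this was not tested either. The 2 such CHH windows, also named after their values were seen and not tested, were at 13360401 to 13360600 on chromosome 1 (12.6% in Col, 0.865% in crt1-4 and 23.4% in crh6-3) and at 11026201 to 11026400 on chromosome 5 (24.5%, 14.1% and 39.4%).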

How the results depend on the processing

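The corrections for unmethylated windows, the log2 ratio of class means and all uses of recovered contacts were chosen only after the data were seen. No paired analysis was possible because each group analysed had 1 library, and no result here comes from a test. Depth limits Hi-C most at 50 kb, where 31.4% of pairs in WT and 45.0% in crh6 were 0, and the depth of the bisulfite values is unknown. The minimum of 50 shared cytosines and the other set of cytosines for genes and transposon genes were not run. Of 96 alternatives for methylation levels, 46 moved the value by less than the SD over chromosomes, 39 by more, and 11 turned its sign. Of 36 for window counts, 9 stayed within 1.5-fold and 27 did not. Of 105 for Hi-C classes, 72 moved the value by less than the SD, 30 by more, and 3 turned its sign, and for the other Hi-C results 5 of 9 stayed within it. For the named regions, 33 of 60 stayed on their side of the threshold with 500-bp windows, 25 fell under it, 1 passed it and 1 turned, and of 30 values for named Hi-C bins 19 moved by less than the SD over bins, 10 by more and 1 turned. The CHH change kept its direction in every alternative for genome, pericentromere and arm levels, and contacts within pericentromeres were fewer in crh6 in all 15 alternatives, from -0.47 to -0.18. All 15 use balanced values, so none shows what balancing itself adds to the change. Recovered contacts before balancing fell in about the same proportion within pericentromeres and within arms. Fewer windows under stricter thresholds, more cytosines or longer windows follow from how these are built, and the level differences in the unmethylated windows are what the corrections remove. For all other values below the cause was not tested.

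Methylation differences are in percentage points. With every cytosine that each library lists, crt1-4 minus Col was -0.0251 for genome CHG, 0.550 for pericentromere CG and -0.0858 for arm CHG, and turned to 0.107 for genome CG. For crh6-3 it was -0.233 for genome CHG, -0.703 for pericentromere CHH and -0.238 for arm CHH, and turned to -0.0918 for pericentromere CHG. The mean of 200-kb bin means turned genome CG in crt1-4 to 0.0104. Pericentromeres set by a Col CHG fraction of 0.25 or more gave crt1-4 values of 0.502 for pericentromere CG, -0.0868 for arm CHG and -0.169 for arm CHH. In crh6-3 they gave 0.520 for pericentromere CG, -0.680 for pericentromere CHH, -0.256 for arm CHG and -0.246 for arm CHH. Pericentromeres set by a Col CG fraction of 0.5 or more gave -0.236 for arm CHH in crh6-3.

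Levels corrected for unmethylated windows gave crt1-4 values of -0.0302 for arm CG, -0.00846 for arm CHG, -0.0774 for genome CHH, -0.290 for pericentromere CHH and -0.0322 for arm CHH. Genome CG turned to 0.0588 and genome CHG to 0.0274. In crh6-3 they gave -0.0234 for arm CG, -0.00245 for genome CHG, 0.172 for pericentromere CHG and -0.0366 for arm CHG. CHH was -0.129 for the genome, -0.479 for pericentromeres and -0.0546 for arms, and genome CG turned to 0.0588. With the level of unmethylated windows subtracted, crt1-4 had 0.537 for pericentromere CG, -0.0159 for arm CG, 0.236 for pericentromere CHG and -0.00668 for arm CHG. CHH was -0.0750 for the genome, -0.280 for pericentromeres and -0.0314 for arms, while genome CG turned to 0.0812 and genome CHG to 0.0329. In crh6-3 subtraction gave 0.589 for pericentromere CG, 0.240 for pericentromere CHG, -0.0318 for arm CHG, -0.126 for genome CHH, -0.466 for pericentromere CHH and -0.0534 for arm CHH. Genome CG turned to 0.110, arm CG to 0.00828 and genome CHG to 0.0127.

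Windows of 100 bp gave 7860 CG, 2295 CHG and 3199 CHH windows in crt1-4, and 5940, 2787 and 3650 in crh6-3. Windows of 500 bp gave 438 CG, 404 CHG and 127 CHH windows in crt1-4, 374, 498 and 149 in crh6-3, and 158, 197 and 64 shared by both. With 500-bp windows the CHH region at 16693401 on chromosome 3 turned to -0.340 percentage points in crt1-4. At least 10 shared cytosines gave 627 CG and 174 CHG windows in crt1-4, 430 and 239 in crh6-3, and 136 and 76 shared by both. Thresholds of 0.5, 0.3 and 0.2 gave 1455 CG, 272 CHG and 53 CHH windows in crt1-4, and 1069, 331 and 65 in crh6-3.

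Hi-C changes are in log2. Pericentromeres set by a Col CHG fraction of 0.25 or more gave -0.47 within pericentromeres, -0.17 between pericentromeres and -0.055 for pericentromere with arm of the same chromosome, where a Col CG fraction of 0.5 or more gave -0.072. The 50-kb matrices gave -0.15 for pericentromere with arm of the same chromosome, -0.24 within arms, -0.17 for opposite arms and -0.12 for arms of different chromosomes. They gave -0.44 within pericentromeres and -0.11 within arms at 1 to 2 Mb, and turned pericentromere with arm of other chromosomes to -0.049. These are means of log2 values with 0.1 added, and the 50-kb log2 ratio of means for that last class was not turned, at 0.060. Medians over bin pairs gave 0.036 for pericentromere with arm of other chromosomes, -0.16 within arms and -0.045 for arms of different chromosomes. Without the bins of lowest and highest spread, the values were -0.059 between pericentromeres, -0.098 for pericentromere with arm of the same chromosome and 0.039 with arm of other chromosomes. Centring on all non-neighbouring pairs subtracted their mean of -0.055 and so raised every value. It gave -0.055 between pericentromeres, -0.030 for pericentromere with arm of the same chromosome and 0.074 with arm of other chromosomes. It gave -0.14 within arms, -0.024 for opposite arms and -0.0030 for arms of different chromosomes. The log2 ratio of class means was 0.070 for pericentromere with arm of other chromosomes, -0.12 within arms and -0.036 for arms of different chromosomes. Recovered contacts balanced anew without the same and neighbouring bins gave -0.18 within pericentromeres, 0.11 for pericentromere with arm of other chromosomes, -0.13 within arms, -0.014 for opposite arms and -0.00012 for arms of different chromosomes. At 1 to 2 Mb they gave -0.18 within pericentromeres and -0.0051 within arms. They turned the bin at 14200001 on chromosome 1 to 0.0018. They also turned contacts between pericentromeres to 0.0012 and those of pericentromere with arm of the same chromosome to 0.020. With WT thinned to the crh6 total, recovered contacts gave 0.034 for pericentromere with arm of other chromosomes and -0.049 for arms of different chromosomes.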

Other observations

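The test of the knob of chromosome 4 and the groups of windows and chromosome ends described here were chosen only after the data were seen.

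CG methylation without CHG or CHH, the pattern typical of gene bodies, was found in 43295 windows. Of these, 1.70% passed the CG threshold in crt1-4 and 1.12% in crh6-3, against 0.0996% and 0.127% of the 51216 windows methylated in all contexts. The 2 groups were not matched for level or number of cytosines. Mean CG in Col was 71.7% in the first and 86.8% in the second, which left the second less room to rise. Windows called lower in crt1-4 were 439 in the first and 28 in the second. In the CG-only windows crt1-4 differed the same way from both other libraries in 342 windows, Col in 150 and crh6-3 in 175. The windows methylated in all contexts had a CHH level of 10.8% in Col, 10.4% in crt1-4 and 9.99% in crh6-3.

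Chromosome ends, taken as the outer 1 Mb of each arm, had fewer contacts with pericentromeres of other chromosomes in crh6, with a mean log2 change of -0.14. The values for ends come from the deposited matrices and were not computed without near contacts. That setting raised contacts of pericentromeres with arms of other chromosomes as a whole, so this fall may be smaller there. The left ends of chromosomes 2 and 4, which carry the ribosomal RNA genes, stood apart, with -0.0033 for contacts with pericentromeres. Their contacts with each other had 0.17 over 25 pairs, where the mean value was 2.04 in WT and 2.44 in crh6. These ends also lie close to a pericentromere, which begins at 1200001 on chromosome 2 and at 1600001 on chromosome 4. Position and ribosomal RNA genes can therefore not be told apart. The bin at 700001 to 750000 on chromosome 1 had values in the WT matrix alone, where it held 16312 recovered contacts against a median of 9588 per bin. The bin at 12750001 on chromosome 1, with 2145 contacts, was also kept in WT alone. Bins kept in crh6 alone were at 1 and 5200001 on chromosome 2, 3200001 on chromosome 4, and 11800001 and 11850001 on chromosome 5. They held 959 to 1474 contacts against a median of 6019.5.

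The short arm of chromosome 4 carries a heterochromatic knob, which lies in the block at 1600001 to 2400000. Its contacts with the pericentromere at 2800001 to 6000000 had a mean value of 6.60 in WT and 4.93 in crh6. The hypothesis that the knob loses contacts with the pericentromere beyond what arm bins at the same distances lose was consistent with a difference of -0.36 on the log2 scale, from -0.35 for the knob and 0.01 for the arm. When near contacts were left out before balancing, the knob value was -0.19 and the arm value 0.12, so that the difference of -0.31 then came in good part from the arm. Knob pairs belong to the pericentromeric class whose change had already been seen, so the test is not independent of it. It also rests on balanced values, which a larger pericentromeric share of contact ends in crh6 lowers.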
